A study of Homo sapiens with 18 samples.

How the data were processed

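Total RNA from 18 samples of human lymphoma cell lines was labelled with biotin and hybridised to Affymetrix whole-transcript arrays. The samples form 6 groups of 3. L428 is a cell line from classical Hodgkin lymphoma, a tumour of B-cell origin that has lost most of the B-cell program. L428-PAX5 is a derivative in which mifepristone induces PAX5, the transcription factor that commits cells to the B lineage. L428+M and L428-PAX5+M were given 0.25 nM mifepristone and had a treatment time of 5 days. L428+MAT and L428-PAX5+MAT had mifepristone for 2 days, then 3 µM 5-aza-2'-deoxycytidine (5-aza-dC, which blocks DNA methylation) for 3 days, with 640 nM trichostatin A (TSA, a histone deacetylase inhibitor) for the last 24 hours. Raji and Namalwa are Burkitt lymphoma lines and were untreated, so that cell line and mifepristone are confounded wherever they are compared with L428. Per the labels' protocols, the medium of L428-PAX5 also held HEPES, which adds a culture difference to each comparison of L428-PAX5 with L428. Groups and replicate numbers were taken from the labels. The titles of the 3 L428-PAX5+MAT samples name L425-PAX5 while their cell line field names L428-PAX5, and the field was followed. The labels do not say whether replicates are separate cultures, so p-values measure the spread between these samples, which may be technical.

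The deposited values are log2 expression values per probe set; per the submitters' processing notes, RMA and Partek were used, with versions and the order of steps not given in the sources used here. The table holds 33297 probe sets with no missing values, from 2.24 to 14.64, and array medians lie between 6.52 and 6.70. No detection calls were used, and signal near the floor is compressed by background correction, so changes of dim genes are understated. In the platform annotation, 19460 probe sets carry exactly 1 gene symbol, 1754 carry several and 12083 are not listed and are unnamed here. The single gene identifiers of 19429 probe sets matched the reference gene table (RefSeq, assembly GRCh38.p14), and no symbol changed. Only probe sets with 1 symbol were used, with the brightest on average kept for each of the 769 genes that had more than 1, which left 18417 genes. The array build is not given in the sources used here, so no coordinates are reported, and the assembly served only for names and the order of neighbouring genes.

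Changes were estimated with limma 3.58.1 (lmFit and eBayes, no trend) in R 4.3.3, with 1 mean per group over all 18 arrays, 12 residual and 6.1 prior degrees of freedom. Tests are two-sided with Benjamini-Hochberg adjustment over the 18417 genes of each comparison. A gene passes at an adjusted p below 0.05, and the number that also change at least 2-fold is given beside the count. Changes are log2 differences of group means with their standard error (SE). Tables and plots were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Precision is limited by the number of arrays.

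The comparisons, tests, alternatives, 24 gene lists and the rule for named genes were fixed before the data were examined. The rule takes PAX5 first, then the 8 largest rises and 8 largest falls among passing genes whose values do not overlap between the groups and whose higher group mean lies above the median of all values, up to 2 rising and 2 falling members per list, and a fixed set of B-cell, plasma-cell and Hodgkin genes. For the interaction it takes the 5 largest changes in each direction. Members of families with near-identical sequences (immunoglobulin, HLA class II, cancer-testis SSX and MAGE, histones) may share signal with one another, and their values are uncertain in that respect. The lists cover B-cell identity and receptor signalling, B-cell transcription factors, germinal-centre B cells, genes reported as activated and as repressed by PAX5, plasma cells, immunoglobulin, HLA class II, Hodgkin cells, NF-kB targets, T and NK cells, myeloid cells, fibroblast and epithelial cells, cancer-testis genes, the interferon response, p53 and growth arrest, the cell cycle, MYC and ribosome biogenesis, DNA methylation and histone deacetylation machinery, replication-independent and polyadenylated histones, apoptosis regulators, heat shock and the unfolded protein response, neuronal genes, and glucocorticoid and progesterone receptor targets. Each was tested as a set with limma's camera (inter-gene correlation preset to 0.01), adjusted over the 24 lists of a comparison, and again with an estimated correlation.

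Genes at least 2-fold higher than L428+M in both Raji and Namalwa, each with a passing test, are called B-cell genes below. The name is only a label, since these genes may also differ by line or by mifepristone, which Raji and Namalwa were not given. L428+M enters both the definition of these genes and the test of their rise, so the share of the gap closed by unchanged groups was simulated against the same controls 100 times.

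Whether equal replicate numbers mark paired samples was checked by correlating the deviations of arrays from their group means across genes. Of the 45 pairs of arrays with equal numbers in different groups, 38 correlated above 0.1, with a range from -0.01 to 0.66. All such pairs among the groups derived from L428 and between Raji and Namalwa were above 0.1, while some pairs of an L428-derived group with Raji or Namalwa were not. The first component of the deviations held 39.9% of their variance and set the arrays numbered 3 apart, and 16 of 18 arrays correlated best with an array of their own number. The replicate number, which comes from the titles, was therefore taken as pairing samples within the L428-derived groups and between Raji and Namalwa only, and the value with the number as a block is given where it changes a list's call or moves a printed count of a comparison or a list by more than 1.5 times, for comparisons within the L428-derived groups. List counts of 2 or fewer, 0 included, often moved by 1 or more when 1 array was left out.

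The method was tested on simulated data with 50 genes changed at each of 4 sizes among 18417. For the PAX5 effect without drugs it recovered 16% of changes of 0.5, 76% of changes of 1 and 100% of changes of 2 (log2), and 5.2% of its calls were false. For the interaction the shares were 2%, 48% and 96%, with 8.2% of calls false, so that many true interactions of 2-fold would be missed. The simulated noise was independent between genes and arrays, without the deviations that equal replicate numbers share here. The rates may therefore differ in the real data. The alternatives were 2 other array scalings, all probe sets, the mean probe set per gene, a filter on dim probe sets, only the groups compared, an intensity trend with robust priors, array weights, the replicate block, a 2-fold limit, other definitions of B-cell genes and the omission of each array in turn. Omission of the arrays numbered 3, and of L428-PAX5+MAT arrays 2 and 3, was added after seeing the data.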

Results

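The samples ask how far renewed PAX5 expression, alone or with drugs that open chromatin, brings back B-cell gene expression in a Hodgkin lymphoma line. Expression of 18417 genes was measured on 18 arrays, 3 for each of L428 with mifepristone (L428+M), PAX5-inducible L428 with mifepristone (L428-PAX5+M), both lines with mifepristone, 5-aza-dC and TSA (L428+MAT and L428-PAX5+MAT), and the Burkitt lines Raji and Namalwa. Replicate arrays correlated across genes with r from 0.9628, for L428-PAX5+MAT replicates 2 and 3, to 0.9961, for Raji replicates 1 and 2. No pair of arrays held identical values.

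PAX5 itself separated the groups as their labels state. Its log2 signal was 12.70, 12.81 and 12.68 in L428-PAX5+M and 12.84, 12.85 and 12.67 in L428-PAX5+MAT. L428+MAT had 7.08, 7.14 and 7.28, and L428+M had 8.64, 7.14 and 6.7, with replicate 1 above the other 2. Raji had 10.97, 10.94 and 10.77 and Namalwa 11.31, 11.07 and 10.85. PAX5 was thus 37.6-fold higher in L428-PAX5+M than in L428+M (5.23 ± 0.30, log2 change ± SE, n = 3 per group, limma adjusted p = 1.30e-09) and lay above both B-cell lines on every L428-PAX5 array. The drugs did not change it by a passing amount in L428 (-0.33 ± 0.30) or in L428-PAX5 (0.06 ± 0.30).

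**Figure D1:**
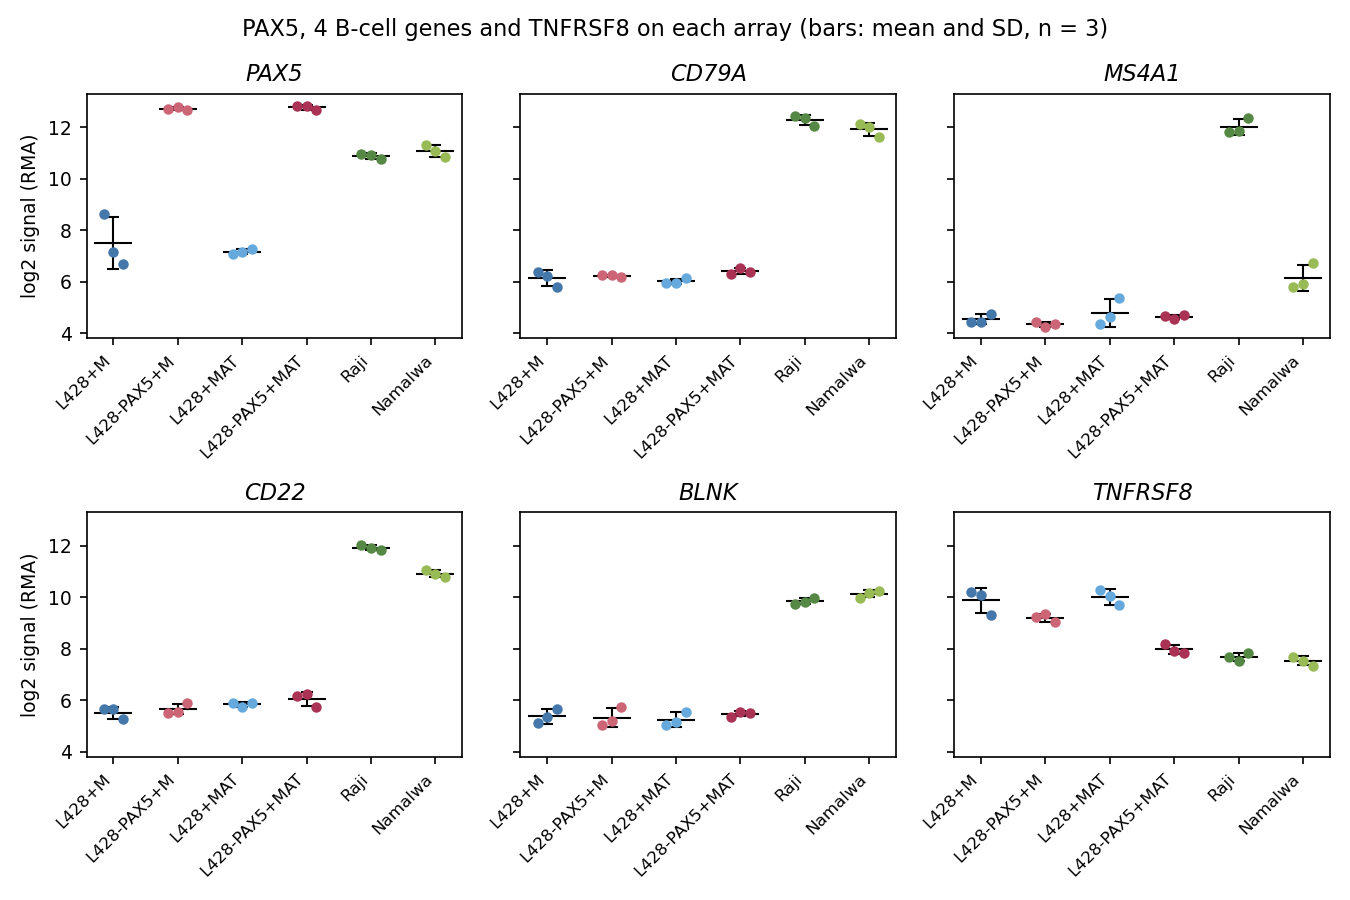
Log2 signal (vertical axis) of PAX5, CD79A, MS4A1, CD22, BLNK and TNFRSF8 on each array, by group, where points are arrays and bars the mean and SD (n = 3). PAX5 lay between 12.67 and 12.85 on the L428-PAX5 arrays, while group means of CD79A were 6.13 in L428+M and 6.23 in L428-PAX5+M.

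Raji and Namalwa together were set against L428+M to define the B-cell expression that the Hodgkin line lacked. The chains of the B-cell receptor and its signalling partners stood far higher in the B-cell lines. CD79A was 63.3-fold higher (5.98 ± 0.14, log2 ± SE, n = 6 against 3), the receptor modulator CD22 60-fold (5.91 ± 0.14), the adaptor BLNK 24.7-fold (4.63 ± 0.16), MS4A1 (CD20) 23.1-fold (4.53 ± 0.21) and CD79B 17.4-fold (4.12 ± 0.13). The lines were not alike in MS4A1, whose mean log2 signal was 12.03 in Raji, 6.13 in Namalwa and 4.55 in L428+M. The largest rises were those of JCHAIN, the joining chain of polymeric immunoglobulin (7.28 ± 0.16), ARHGDIB (7.22 ± 0.13), PLAC8 (6.92 ± 0.16), CYTIP (6.45 ± 0.13) and CD180 (6.35 ± 0.11). SH2D1B, an adaptor of SLAM receptors (-7.63 ± 0.30), GTSF1 (-7.51 ± 0.14), CYP4Z1 (-7.46 ± 0.22), the chemokine CCL1 (-7.15 ± 0.28) and the phospholipase PLA2G4A (-7.05 ± 0.25) were lowest relative to L428. TNFRSF8, the Hodgkin marker CD30, was lower by 4.83-fold (-2.27 ± 0.18) and PRDM1, a plasma-cell regulator, by 4.79-fold (-2.26 ± 0.14). In all, 6526 of 18417 genes passed limma with Benjamini-Hochberg adjustment, 3453 higher and 3073 lower, and 2663 of them changed at least 2-fold. Raji and Namalwa had no mifepristone, so line and mifepristone were confounded.

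Among the lists of B-lineage genes, 23 of 28 measured members for B-cell identity and receptor signalling were higher and 2 lower (CD24 and FCER2), with 3 not passing (camera adjusted p = 7.14e-16). The germinal-centre list had 11 of 14 higher, none lower and 3 not passing (adjusted p = 3.01e-10), led by STAP1 (6.12 ± 0.20) and TCL1A (5.88 ± 0.16). B-cell transcription factors had 11 of 18 higher, 1 lower and 6 not passing (adjusted p = 9.32e-05, and adjusted p = 0.0573 with an estimated correlation). Genes reported as activated by PAX5 had 12 of 18 higher and 3 lower (adjusted p = 6.71e-05), and those reported as repressed by PAX5 had 3 higher, 4 lower and 11 not passing (adjusted p = 0.817). All 3 measured immunoglobulin genes were higher (adjusted p = 7.51e-04). The plasma-cell list had 9 of 20 higher and 5 lower (adjusted p = 0.36), and the HLA class II list had 4 of 13 higher and 4 lower (adjusted p = 0.885), of which 2 were called lower without L428+M replicate 1. Adjusted over the list alone, the counts were 12 higher and 1 lower for transcription factors, 11 and 1 for the germinal-centre list, 13 and 3 for activated genes, 9 and 6 for plasma cells, and 4 and 5 for HLA class II, and those of the other lists in this paragraph stayed as given. Without L428+M replicate 2, 1 B-cell identity gene was lower instead of 2.

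The Hodgkin-cell list had 25 of 29 members lower and 1 higher (adjusted p = 3.21e-20), with IL13RA1 at -6.97 ± 0.18 and MSC, an inhibitor of B-cell transcription factors, at -6.14 ± 0.20. NF-kB targets had 15 of 28 lower and 2 higher (adjusted p = 5.01e-07, and adjusted p = 0.0684 with an estimated correlation). The interferon response had 21 of 30 lower and 4 higher (adjusted p = 1.44e-08). MYC and ribosome biogenesis had 14 of 21 higher and 1 lower (adjusted p = 0.00256, and adjusted p = 0.275 with an estimated correlation), histones had 1 of 13 higher and 7 lower (adjusted p = 0.00447, and adjusted p = 0.129 with an estimated correlation), and heat shock genes had 4 of 22 higher and 9 lower (adjusted p = 0.0271, and adjusted p = 0.122 with an estimated correlation). Adjusted over the list alone, the counts were 25 lower and 1 higher, 16 and 3, 22 and 4 for the first 3 of these lists, then 14 higher and 2 lower, 1 and 9, and 4 and 10.

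The remaining lists did not pass camera in this comparison. T and NK cell genes had 3 of 23 higher and 3 lower (adjusted p = 0.885), myeloid genes 5 of 23 and 3 (0.824), fibroblast and epithelial genes 0 of 20 and 2 (0.293), cancer-testis genes 1 of 24 and 3 (0.625), p53 and growth arrest genes 7 of 23 and 5 (0.625), and cell cycle genes 8 of 29 and 8 (0.73). The counts for the cell cycle fell to 5 higher without L428+M replicate 2 and to 5 lower without L428+M replicate 3. DNA methylation and histone deacetylation machinery had 4 of 22 higher and 4 lower (adjusted p = 0.508), apoptosis regulators 7 of 23 and 9 (0.625), neuronal genes 1 of 22 and 5 (0.207), and glucocorticoid and progesterone receptor targets 2 of 14 and 5 (0.325). Adjusted over the list alone, the counts differed for T and NK cells (3 and 2), p53 and growth arrest (8 and 5), the cell cycle (9 and 9) and the methylation machinery (7 and 4). Median and mean differed in sign for the genes repressed by PAX5 (-0.13 and 0.42), T and NK cells (0.12 and -0.24), myeloid genes (0.02 and -0.11), cancer-testis genes (0.05 and -0.47) and receptor targets (0.08 and -0.42), and camera followed the median in the first 2 and the mean in the last 3.

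PAX5 expression without drugs, L428-PAX5+M against L428+M, left the B-cell receptor genes near their level in L428. CD79A changed by 0.10 ± 0.16 (log2 ± SE, n = 3 per group, adjusted p = 0.781), CD22 by 0.13 ± 0.16 (0.683), BLNK by -0.05 ± 0.18 (0.912), MS4A1 by -0.21 ± 0.25 (0.678), CD79B by -0.24 ± 0.15 (0.379) and POU2AF1 by -0.02 ± 0.17 (0.971), and none of these passed. The genes most above L428+M were the cytokine IL31 (24.6-fold, 4.62 ± 0.29), ICA1L (4.29 ± 0.31), the actin regulator ENAH (4.0 ± 0.26), the ephrin receptor EPHA3 (3.99 ± 0.19) and UTRN (3.87 ± 0.27). EVI2B (53-fold lower, -5.73 ± 0.18), ENTREP1 (-5.42 ± 0.17), the annexin ANXA1 (-5.35 ± 0.20), the aromatase gene CYP19A1 (-4.84 ± 0.24) and TSPAN8 (-4.60 ± 0.25) were furthest below it. In all, 2996 genes passed, 1790 higher and 1206 lower, and 881 changed at least 2-fold, 500 of them higher. L428-PAX5 without induction was not analysed here, so PAX5, cell line and medium are confounded in each comparison of L428-PAX5 with L428.

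HLA class II genes, which present antigen to T cells, were lower in L428-PAX5+M than in L428+M. Of 13 measured members 9 were lower, none higher and 4 did not pass, also when adjusted over the list alone (camera adjusted p = 2.13e-06, and 0.00253 with an estimated correlation), with HLA-DMA at -1.56 ± 0.20, HLA-DOA at -1.31 ± 0.13 and their activator CIITA at -1.13 ± 0.18. The germinal-centre list had 5 of 14 lower and none higher, also adjusted over the list alone (adjusted p = 9.37e-04, and 0.0178 with an estimated correlation), with GCSAM at -2.12 ± 0.17 and the repressor BCL6 at -1.99 ± 0.16. MYC and ribosome biogenesis genes had 10 of 21 higher and 2 lower, and 12 and 2 adjusted over the list alone (adjusted p = 1.10e-04, and adjusted p = 0.319 with an estimated correlation), with RRS1 at 2.00 ± 0.23 and ODC1 at 1.37 ± 0.22. No other list passed camera, whose other adjusted p-values started at 0.27. B-cell identity genes had 2 of 28 higher, CD53 (2.03 ± 0.18) and the complement receptor CR2 (1.80 ± 0.22), and 4 lower (adjusted p = 0.578), with the same counts adjusted over the list alone. The lower count was 2 without L428-PAX5+M replicate 2 and 7 without the arrays numbered 3. The Hodgkin-cell list had 5 of 29 higher and 10 lower, unchanged when adjusted over the list alone (adjusted p = 0.365), and the lower count was 5 without L428+M replicate 1 or 2 and 6 without L428-PAX5+M replicate 2 or 3. Its leading members were CSF1R (2.69 ± 0.18), CD274 (1.58 ± 0.23), IL5 (-4.07 ± 0.41) and LGALS1 (-1.75 ± 0.15).

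Of the regulators of plasma-cell and Hodgkin identity, PRDM1 changed by -0.85 ± 0.16 on the log2 scale (adjusted p = 9.54e-04) and XBP1 changed by 0.28 ± 0.18 (0.356). TNFRSF8 changed by -0.67 ± 0.21 (adjusted p = 0.0318). That call was lost without L428+M replicate 1 (-0.50) or 2 (-0.55) and without L428-PAX5+M replicate 1 (-0.69) or 3 (-0.58). ID2, which blocks E-protein transcription factors, changed by -0.92 ± 0.26 (adjusted p = 0.0201), a call lost without L428+M replicate 1 (-0.75) or 2 (-0.88) and without L428-PAX5+M replicate 2 (-0.88) or 3 (-0.74). These tests did not use the pairing by replicate number. In the order of the numbers, ID2 was 11.57, 11.3 and 10.78 in L428+M and 10.74, 10.22 and 9.93 in L428-PAX5+M, lower in each pair. TNFRSF8 was also lower in L428-PAX5+M in each pair.

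In L428 without induced PAX5, the drugs raised germ-cell genes and interferon-response genes. The cancer-testis gene SSX1 rose 41.7-fold (5.38 ± 0.18, log2 ± SE, n = 3 per group), TKTL1 33.4-fold (5.06 ± 0.22), SSX3 28.9-fold (4.85 ± 0.22), ATP1B2 26.1-fold (4.71 ± 0.28), the meiotic gene HORMAD1 24.1-fold (4.59 ± 0.35) and the germ-cell RNA-binding gene DAZL 20.8-fold (4.38 ± 0.28). The falls were smaller, with MINAR2 at -1.78 ± 0.27, PTPRR at -1.37 ± 0.24 and ADGRL2 at -1.35 ± 0.20. In all, 892 genes passed limma, 775 higher and 117 lower, and 368 changed at least 2-fold, 355 of them higher. With the replicate number as a block 1592 genes passed, with only the 2 groups in the fit 593, and with array weights, whose estimation stopped before its tolerance was reached, 2551.

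Interferon-response genes had 21 of 30 members higher, none lower and 9 not passing, and 27 higher adjusted over the list alone (camera adjusted p = 1.54e-38, and 1.09e-04 with an estimated correlation). Their median rise was 1.11, with MX1, an antiviral GTPase, at 2.59 ± 0.21 and IFI27 at 2.37 ± 0.20. Cancer-testis genes had 9 of 24 higher and none lower, and 14 higher adjusted over the list alone (adjusted p = 8.31e-21, and 0.00553 with an estimated correlation). Genes reported as activated by PAX5 had 4 of 18 higher and none lower, and 7 adjusted over the list alone (adjusted p = 3.39e-04, and 0.0217 with an estimated correlation), with CR2 at 2.02 ± 0.22 and FCER2 (CD23) at 1.60 ± 0.18. That count was 2 without L428+M replicate 2 or 3 or L428+MAT replicate 1, and 2 with array medians subtracted. The same list had 2 higher and 2 lower in L428-PAX5+M against L428+M, also adjusted over the list alone (adjusted p = 0.953, camera direction down, median 0.04 and mean 0.01). It had 3 higher and 9 lower in L428-PAX5+MAT against L428+MAT, and 5 and 9 adjusted over the list alone (median -0.28, adjusted p = 0.278). A block on replicate number made these counts 2 and 4, and 6 and 9, and the higher count of the first was 1 without L428+M replicate 2 or 3 or any 1 of the L428-PAX5+M replicates. NF-kB targets had 7 of 28 higher and none lower, and 10 adjusted over the list alone (adjusted p = 2.94e-09, and adjusted p = 0.0576 with an estimated correlation). Their count was 4 and 2 without L428+M replicates 2 and 3, and 3 and 1 without L428+MAT replicates 1 and 2. It was 3 with array medians subtracted and 12 with the replicate number as a block.

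Smaller shifts upward passed the preset test and were lost with an estimated correlation. They were the Hodgkin-cell list with 4 of 29 higher (adjusted p = 7.46e-04, and adjusted p = 0.138 with an estimated correlation), neuronal genes with 4 of 22 (0.00274 and 0.225), fibroblast and epithelial genes with 4 of 20 (0.0123 and 0.116), p53 and growth arrest genes with 4 of 23 (0.0123 and 0.232), histones with 3 of 13 (0.0173 and 0.225), myeloid genes with 3 of 23 (0.0258 and 0.202) and B-cell identity genes with 3 of 28 (0.0496 and 0.116). None of these lists had a lower member. Adjusted over the list alone the higher counts were 6, 6, 4, 5, 3, 5 and 3, with 1 lower member in each of the first 2. The Hodgkin-cell count was 2 without L428+M replicate 3 or L428+MAT replicate 2, and the p53 count was 2 without L428+MAT replicate 2. With the replicate number as a block, 7 Hodgkin-cell and 6 myeloid genes were higher, and 1 Hodgkin-cell, 1 neuronal and 1 B-cell identity gene were lower. B-cell transcription factors (2 higher, 1 lower of 18, and 5 and 1 adjusted over the list alone) and receptor targets (2 higher of 14, and 2 adjusted over the list alone) both had an adjusted p = 0.0826, which was 0.0435 and 0.0329 with the replicate number as a block, where 4 genes of each list were higher. Neither list passed with an estimated correlation (adjusted p = 0.309 and 0.255, without the block). The higher count of the transcription factors was 0 without L428+M replicate 2 or 3 or L428+MAT replicate 1, 1 without L428+MAT replicate 2, and 0 with array medians subtracted, and that of the receptor targets was 1 without L428+MAT replicate 1. CD79A (-0.11 ± 0.16), CD79B (0.02 ± 0.15), MS4A1 (0.23 ± 0.25), CD22 (0.33 ± 0.16), BLNK (-0.12 ± 0.18), POU2AF1 (0.10 ± 0.17), PRDM1 (-0.03 ± 0.16) and TNFRSF8 (0.14 ± 0.21) did not pass. CDKN1A, the cell-cycle inhibitor p21, rose by 1.14 ± 0.25 (adjusted p = 0.00867), a call lost without L428+MAT replicate 2 (0.97).

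In L428-PAX5, the same drugs changed far more genes, and in both directions. UTS2B, a urotensin gene, rose 84.5-fold (6.40 ± 0.25, log2 ± SE, n = 3 per group), RFPL4A 55.6-fold (5.80 ± 0.32), GPR50 44.6-fold (5.48 ± 0.23), TENM1 30.1-fold (4.91 ± 0.20), TKTL1 28.6-fold (4.84 ± 0.22) and the germ-cell cyclin CCNA1 27.6-fold (4.79 ± 0.22). IL31, 24.6-fold higher in L428-PAX5+M than in L428+M, fell by 4.02 ± 0.29, GPR183, an oxysterol receptor of B cells, by 3.08 ± 0.38, NDST4 by 2.97 ± 0.36 and ABCB10 by 2.69 ± 0.25 on the log2 scale. In all, 6204 genes passed limma, 2622 higher and 3582 lower, and 2033 changed at least 2-fold, 1166 of them lower. Without L428-PAX5+MAT replicates 2 and 3, the pair that agreed least, 3806 passed, and with array weights 9532.

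Cancer-testis genes had 11 of 24 higher and none lower in L428-PAX5 (camera adjusted p = 3.30e-06), neuronal genes 10 of 22 higher and 1 lower (2.07e-04), and receptor targets 7 of 14 higher and 1 lower (0.00369), among them CRISPLD2 (3.95 ± 0.31) and ERRFI1 (3.89 ± 0.32). Fibroblast and epithelial genes had 7 of 20 higher and none lower (adjusted p = 0.033), histones 6 of 13 higher and 2 lower (0.0378), and p53 and growth arrest genes 9 of 23 higher and 4 lower (0.0378), among them the kinase PLK2 (3.66 ± 0.29). MYC and ribosome biogenesis genes had none of 21 higher and 15 lower (adjusted p = 4.72e-05), with RRS1 at -1.49 ± 0.23 and DKC1 at -1.27 ± 0.17. Hodgkin-cell genes had 4 of 29 higher and 13 lower (adjusted p = 0.033), and NF-kB targets 3 of 28 higher and 11 lower (0.033), with the cytokine LTA at -2.23 ± 0.18. With an estimated correlation none of these calls held, and the lowest adjusted p = 0.216 with an estimated correlation. Adjusted over the list alone, the counts were 12 and 1 for neuronal genes, 11 and 4 for p53 and growth arrest, 1 and 17 for MYC, 3 and 13 for NF-kB, and as given for the other lists. Without L428-PAX5+MAT replicates 2 and 3 the higher counts were 5 for p53 and growth arrest and 3 for fibroblast and epithelial genes. Without the arrays numbered 3, p53 and growth arrest had 14 higher and 6 lower. The block on replicate number gave 1 lower cancer-testis gene and 1 higher MYC and ribosome biogenesis gene.

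Interferon-response genes moved both ways in L428-PAX5, 7 higher, 14 lower and 9 not passing of 30, with the same counts adjusted over the list alone (median -0.57, camera adjusted p = 0.199). RIGI, an RNA sensor, rose by 1.59 ± 0.19 and OASL by 1.46 ± 0.17, while IFI44L fell by 2.25 ± 0.34 and OAS2 by 1.88 ± 0.20 on the log2 scale. TNFRSF8 fell by 1.23 ± 0.21 (adjusted p = 1.38e-04), XBP1, a driver of the secretory program, by 1.33 ± 0.18 (1.58e-05) and the lymphoid factor IKZF1 by 2.37 ± 0.27 (2.88e-06), and BCL6 rose by 1.90 ± 0.16 (1.27e-07). CD79A (0.17 ± 0.16), CD79B (0.06 ± 0.15), MS4A1 (0.30 ± 0.25), CD22 (0.40 ± 0.16), BLNK (0.17 ± 0.18) and POU2AF1 (-0.03 ± 0.17) did not pass.

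**Figure D2:**
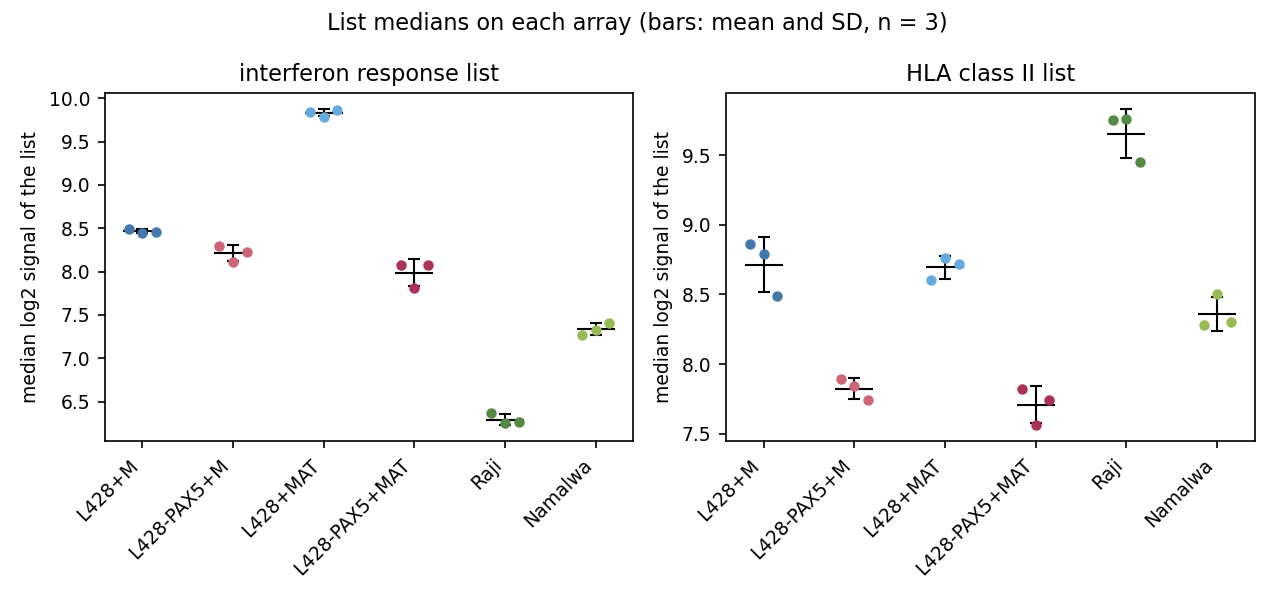
Median log2 signal (vertical axis) of the interferon-response list and of the HLA class II list on each array, by group, where points are arrays and bars the mean and SD (n = 3). The interferon median was 9.79 to 9.87 in L428+MAT, 8.45 to 8.49 in L428+M and 7.81 to 8.08 in L428-PAX5+MAT.

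With the drugs present in both lines, L428-PAX5+MAT had lower interferon, HLA class II and Hodgkin-cell expression than L428+MAT. Interferon genes had 27 of 30 lower and none higher, and 28 lower adjusted over the list alone (camera adjusted p = 4.40e-18, and 0.00207 with an estimated correlation), with IFI44L at -4.37 ± 0.34 and MX1 at -3.89 ± 0.21 (log2 ± SE, n = 3 per group). HLA class II genes had 11 of 13 lower and none higher, also adjusted over the list alone (adjusted p = 2.39e-07, and 0.00199 with an estimated correlation), with HLA-DOA at -1.91 ± 0.13 and HLA-DPB1 at -1.86 ± 0.14. Hodgkin-cell genes had 19 of 29 lower and 4 higher, and 21 and 4 adjusted over the list alone (adjusted p = 2.39e-07, and 0.047 with an estimated correlation), among them the costimulator CD86 at -3.01 ± 0.20 and TNFRSF8 at -2.04 ± 0.21. The higher count was 2 without L428-PAX5+MAT replicate 1. NF-kB targets had 17 of 28 lower and 1 higher, and 18 and 1 adjusted over the list alone (adjusted p = 2.39e-07, and adjusted p = 0.093 with an estimated correlation), with IL6 at -2.67 ± 0.23 and CCL22 at -2.52 ± 0.17.

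B-cell transcription factors had 9 of 18 lower and 1 higher in the same comparison, and 10 and 1 adjusted over the list alone (adjusted p = 0.00248, and adjusted p = 0.161 with an estimated correlation), with TCF4 at -2.14 ± 0.28 and IKZF1 at -1.94 ± 0.27. The plasma-cell list had 8 of 20 lower and 2 higher, and 9 and 2 adjusted over the list alone (adjusted p = 0.0255, and adjusted p = 0.0694 with an estimated correlation), with 5 lower without L428-PAX5+MAT replicates 2 and 3. B-cell identity genes had none of 28 higher and 8 lower, also adjusted over the list alone (adjusted p = 0.165), led by RASGRP3 (-3.48 ± 0.27) and FCER2 (-2.42 ± 0.18). With the replicate number as a block, and without the arrays numbered 3, 3 were higher, and 1 was higher without L428+MAT replicate 1 or L428-PAX5+MAT replicate 2 or 3. PAX5 was 49.2-fold higher, UTS2B 19.4-fold and C1QTNF9B 17-fold, while CYP4Z1 was 55.2-fold, EVI2B 53.8-fold and CYP19A1 47.3-fold lower. In all, 5898 genes passed limma, 2642 higher and 3256 lower, and 2097 changed at least 2-fold. Without L428-PAX5+MAT replicates 2 and 3, 3915 passed, and with array weights 11176.

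The test of the difference itself, the drug effect in L428-PAX5 minus that in L428, passed for 2990 genes, 1039 with a positive and 1951 with a negative difference, and 1624 differed by at least 2-fold. By the signs and sizes of the estimated drug effects, whether or not each passed in its line, 1327 of the 2990 had the same sign in both lines and a larger estimate in L428-PAX5, 106 the same sign and a smaller one, and 1557 opposite signs, 73 of these with a passing change in both lines. UTS2B (4.31 ± 0.35), GPR50 (3.99 ± 0.33), REXO1L1P (3.58 ± 0.66) and the transcription factor SNAI2 (3.53 ± 0.42) had the largest positive differences, and CYP1B1 (-4.41 ± 0.51), IL31 (-3.76 ± 0.42), IFI44L (-3.54 ± 0.49), AVPR1A (-3.47 ± 0.37) and OAS2 (-3.39 ± 0.29) the largest negative ones. Interferon genes had a negative difference in 22 of 30 members and a positive one in none, and 22 and 1 adjusted over the list alone (median -1.78, camera adjusted p = 2.11e-17, and 0.0049 with an estimated correlation). TNFRSF8 (-1.38 ± 0.29, adjusted p = 0.0035) and XBP1 (-1.44 ± 0.25, adjusted p = 9.60e-04) differed, and CD79A (0.29 ± 0.23), CD22 (0.07 ± 0.23), BLNK (0.29 ± 0.26) and PAX5 (0.39 ± 0.43) did not pass. With the replicate number as a block 4730 genes passed, and with array weights 5965. As PAX5 and L428-PAX5 go together, the same contrast is also the change of the PAX5 effect by the drugs.

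**Figure D3:**
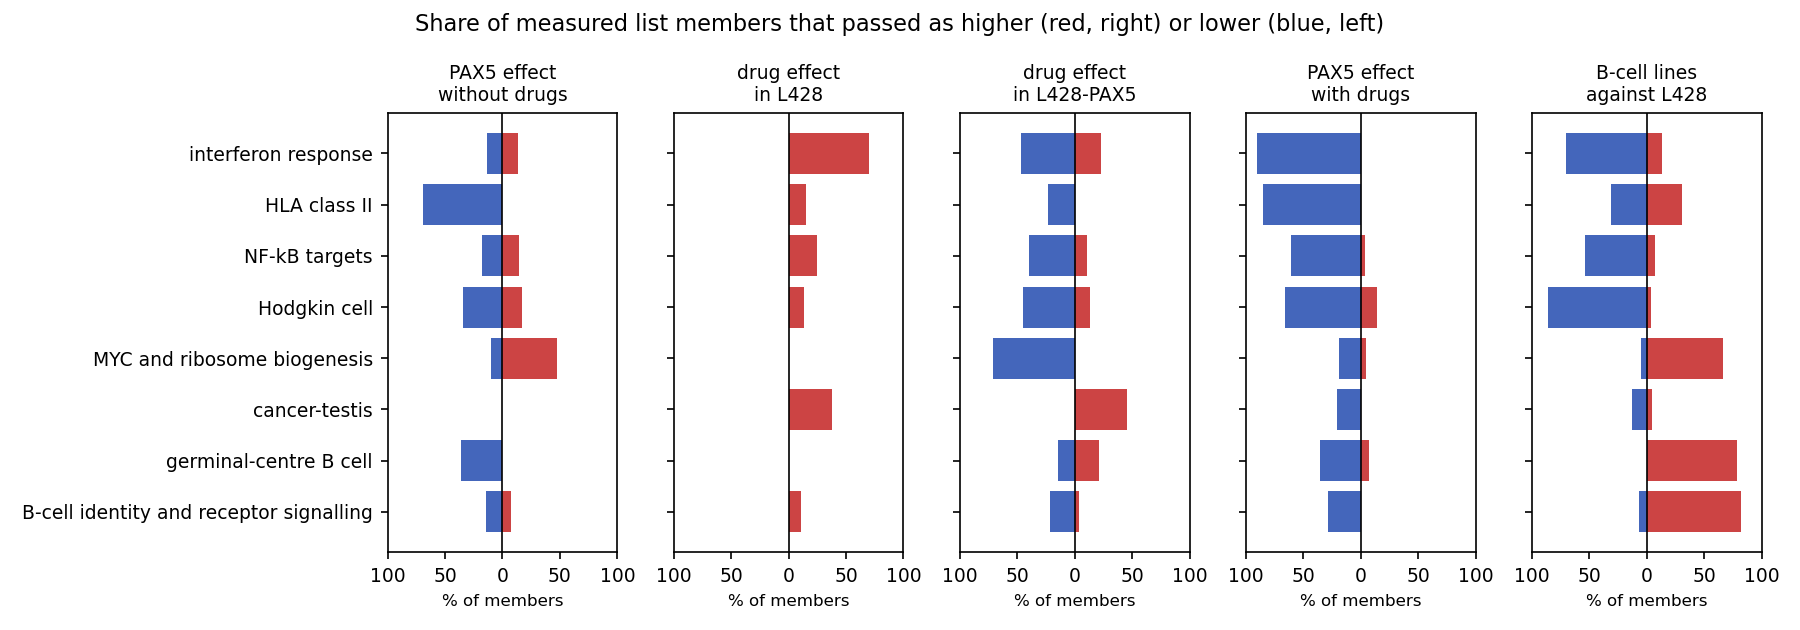
Percentage of measured members (horizontal axis) of 8 gene lists that passed as higher (red, to the right) or lower (blue, to the left) in 5 comparisons. In the interferon list 21 of 30 members were higher with the drugs in L428, and 27 of 30 were lower in L428-PAX5+MAT than in L428+MAT.

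For PAX5 and the drugs together, L428-PAX5+MAT against L428+M, 6899 genes passed, 3290 higher and 3609 lower, with 2629 at least 2-fold. CD22 was 1.44-fold higher (0.53 ± 0.16, log2 ± SE, n = 3 per group, limma adjusted p = 0.013), a call lost without L428+M replicate 3 (0.39) and without L428-PAX5+MAT replicate 1 (0.46) or 2 (0.43). The change against the B-cell lines was 60-fold for the same gene. CD79A (0.27 ± 0.16), CD79B (-0.18 ± 0.15), MS4A1 (0.09 ± 0.25), BLNK (0.11 ± 0.18) and POU2AF1 (-0.05 ± 0.17) did not pass. TNFRSF8 was 3.74-fold lower (-1.90 ± 0.21), IRF8, a factor of the B-cell and myeloid lineages, 4.08-fold higher (2.03 ± 0.28), CR2 3.86-fold higher (1.95 ± 0.22), and RASGRP3 6.65-fold lower (-2.73 ± 0.27). B-cell identity genes had 5 of 28 higher and 7 lower, and 6 and 7 adjusted over the list alone (camera adjusted p = 0.554), with 2 higher without L428+M replicate 3, 3 without L428-PAX5+MAT replicate 1 and 3 with array medians subtracted. HLA class II genes had 10 of 13 lower and none higher, also adjusted over the list alone (adjusted p = 2.72e-05, and 0.00577 with an estimated correlation). Hodgkin-cell genes had 16 of 29 lower and 4 higher, and 17 and 4 adjusted over the list alone (adjusted p = 0.00166, and adjusted p = 0.349 with an estimated correlation). Receptor targets had 8 of 14 higher and 3 lower, also adjusted over the list alone (adjusted p = 0.05, at the limit without passing, 0.0378 with the replicate number as a block, and adjusted p = 0.41 with an estimated correlation and no block).

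Other lists passed the preset test for PAX5 and the drugs together and were lost with an estimated correlation. B-cell transcription factors had 9 of 18 lower and only IRF8 higher (camera adjusted p = 0.0319, and adjusted p = 0.41 with an estimated correlation). NF-kB targets had 11 of 28 lower and 3 higher (0.0426 and 0.55), with 5 higher after quantile normalization. Interferon genes had 15 of 30 lower and 5 higher (0.0426 and 0.416), and the higher count was 3 without any 1 of the L428+M replicates, 2 without L428-PAX5+MAT replicate 1 and 2 with array medians subtracted. Cancer-testis genes had 11 of 24 higher and 1 lower (3.00e-05 and 0.349), p53 and growth arrest genes 11 of 23 higher and 3 lower (0.0298 and 0.41), and neuronal genes 9 of 22 higher and 2 lower (0.0298 and 0.416). The interferon count was 7 higher and 15 lower and the p53 count 11 and 4 when adjusted over the list alone, and the others were as given.

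Genes that passed as at least 2-fold higher than L428+M in both Raji and Namalwa numbered 781. They included 8 B-cell transcription factors, 10 germinal-centre genes and 15 of 28 measured members of the B-cell identity list. The identity list as a whole had 2 higher and 4 lower in L428-PAX5+M than in L428+M, 3 and 0 in L428+MAT, and 5 and 7 in L428-PAX5+MAT. Of the 781 genes, 196 (25.1%) were higher and 51 lower in L428-PAX5+M than in L428+M, 81 (10.4%) higher and 4 lower in L428+MAT, and 289 (37.0%) higher and 107 lower in L428-PAX5+MAT. Of the 17636 other genes, 9.0%, 3.9% and 17.0% were higher, so that B-cell genes were higher more often, with odds ratios of 3.37, 2.82 and 2.86 by Fisher's exact test (two-sided p = 2.07e-37, 4.50e-14 and 1.76e-38, across genes, which are not independent replicates). Independent lists would share 75.9, 32.9 and 139.5 higher genes. The other genes were not matched for their signal in L428+M, while the B-cell genes were chosen for a low one there. Part of the excess may therefore reflect more room to rise. The median share of the gap to the B-cell lines that was closed was 6.5% in L428-PAX5+M, 4.5% in L428+MAT and 10.1% in L428-PAX5+MAT, against 1.38% for unchanged groups simulated against the same L428+M arrays. At least 50% of the gap was closed for 118, 29 and 157 genes. The 3 L428+M arrays were not split between definition and test, so part of the excess may come from the shared controls. When B-cell genes were defined against L428+MAT instead, whose arrays do not enter the PAX5 test, 162 of 801 (20.2%) were higher in L428-PAX5+M than in L428+M. Among all 18417 genes 1790 were higher, and no odds ratio was computed for this definition. At a limit of 4-fold in both lines, 41, 44 and 85 of 221 genes were higher, and the median share closed was 0.5%, 6.1% and 6.7%. The 0.5% in L428-PAX5+M lay below the 1.38% of unchanged groups, which were simulated for the 2-fold limit. At 2-fold the shares were 3.9%, 3.9% and 9.1% after quantile normalization. They were 5.7%, 2.8% and 6.9% with array medians subtracted, against a highest simulated share of 2.28%. Other settings gave higher shares in L428-PAX5+M. With all probe sets tested the shares were 10.5%, 5.5% and 14%. Without L428+M replicate 1, where 833 genes met the definition, the shares were 10.8%, 6.4% and 9.8%. Omission of L428+M replicate 2 gave 7.8%, 5.6% and 10%, and omission of replicate 3 gave 7.5%, 6.2% and 11.8%.

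**Figure D4:**
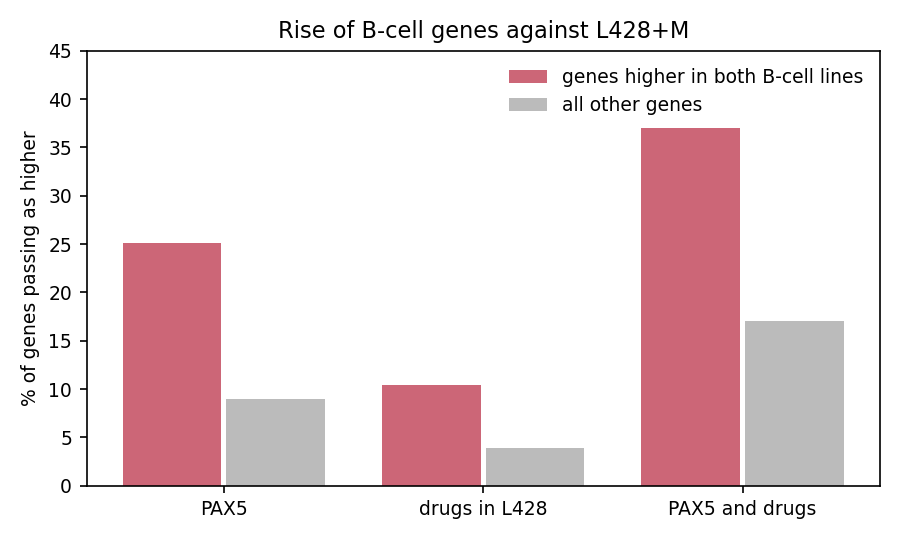
Percentage of genes that passed as higher than in L428+M (vertical axis) in L428-PAX5+M (PAX5), L428+MAT (drugs) and L428-PAX5+MAT (both), for genes at least 2-fold higher in both B-cell lines (red) and for all other genes (grey). The B-cell genes reached 25.1%, 10.4% and 37.0% and the other genes 9.0%, 3.9% and 17.0%.

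Set against the same B-cell lines, L428-PAX5+M differed in 6839 genes, 3249 higher in the B-cell lines and 3590 lower (2653 at least 2-fold), and L428-PAX5+MAT in 9123, 4876 higher and 4247 lower (3843 at least 2-fold). B-cell identity genes were higher in the B-cell lines than in L428-PAX5+M for 24 of 28 members and lower for 1, and higher than in L428-PAX5+MAT for 24 and lower for 2 (camera adjusted p = 3.25e-17 and 1.90e-13, also past the limit with an estimated correlation). HLA class II genes were higher in the B-cell lines than in L428-PAX5+MAT for 11 of 13 members and lower for none (adjusted p = 1.58e-04, and 0.00567 with an estimated correlation). These counts were the same when adjusted over the list alone. Raji and Namalwa differed from each other in 3545 genes, 1426 higher and 2119 lower in Raji, with 1431 at least 2-fold. Interferon genes had 13 of 30 lower and 4 higher in Raji, and 15 and 4 adjusted over the list alone (adjusted p = 6.69e-05, and adjusted p = 0.10 with an estimated correlation). B-cell identity genes had 13 of 28 higher and 5 lower in Raji (0.0101 and 0.0719), NF-kB targets 11 of 28 and 1 (2.64e-04 and 0.204), the plasma-cell list 2 of 20 and 8 (0.0136 and 0.0719) and HLA class II genes 5 of 13 and 1 (0.017 and 0.0754), so the 2 lines are not alike in these lists. These counts were 12 and 1 for NF-kB targets and 5 and 2 for HLA class II when adjusted over the list alone, and as given for the other 2.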

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

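The tests of array scaling, of single arrays, of weaker drug exposure and of the starting level, a second draw of 60 splits and a draw of splits within replicate numbers, were chosen only after the results they bear on were seen. The results in this part differ between the lines L428 and L428-PAX5 by a test of the difference itself, the drug effect in L428-PAX5 minus that in L428.

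The drug effect differed between the lines for 2990 genes. By list, 22 of 30 interferon genes, 12 of 29 Hodgkin-cell genes, 12 of 28 NF-kB targets, 9 of 21 MYC and ribosome biogenesis genes and 4 of 18 B-cell transcription factors had a lower drug effect in L428-PAX5, and 4 of 14 glucocorticoid and progesterone receptor targets a higher one. The camera adjusted p was 2.11e-17, 1.60e-05, 8.30e-08, 1.03e-04, 0.047 and 0.0309 in the same order, and 0.0049, 0.118, 0.118, 0.209, 0.363 and 0.209 with an estimated correlation. Adjusted over the list alone, the counts were 22, 16, 18, 12, 7 and 5. The count for B-cell transcription factors was 8 without L428-PAX5+MAT replicate 3, and 10 with the replicate number as a block and without the arrays numbered 3. Of 132 genes named in the drug comparisons and the interaction, 74 differed between the lines and are given below. Of these, 24 had a positive and 50 a negative difference (SE 0.19 to 0.66, limma adjusted p from 2.98e-07 to 0.0486, n = 3 per group). Some were named for this difference. A gene named for a large rise in L428 is favoured to have a negative difference. A gene named for a large rise in L428-PAX5 is favoured to have a positive one. The signs of such genes are therefore not separate evidence.

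Among the named germ-cell genes, the differences (log2) were -1.43 for SSX1, -1.34 for SSX3, -2.51 for HORMAD1, -1.73 for GCNA and -1.62 for DAZL, but 2.55 for CCNA1. All but CCNA1 were named for a large rise in L428, and CCNA1 for one in L428-PAX5, which favours these signs. Of the 24 cancer-testis genes, 4 had a passing negative difference and none a positive one, and the list did not pass (camera adjusted p = 0.239). Interferon genes differed by -3.31 for MX1, -2.12 for IFI27, -3.54 for IFI44L and -3.39 for OAS2. B-cell, plasma-cell and lymphoid genes with a negative difference were CR2 (-1.87), FCER2 (-1.94), CD38 (-2.82), XBP1 (-1.44), CD53 (-1.66), RASGRP3 (-2.30), IKZF1 (-2.46), TCF4 (-1.60), RGS13 (-1.45), GPR183 (-2.73), SH2D1A (-1.97), EMB (-2.02) and ITGA4 (-1.53). Positive differences in these groups were those of CD24 (1.29), ETS1 (1.05), BCL6 (1.65), ELL3 (0.89), NEDD9 (1.73) and the plasma-cell gene AQP3 (1.62). Genes of Hodgkin cells, inflammation and antigen presentation differed by -1.38 for TNFRSF8, -2.61 for CCL22, -1.81 for CCL17, -3.04 for LTA, -2.35 for STAT5A, -1.15 for AIF1, -0.60 for HLA-DOA and -1.42 for RFX5, and by 1.25 for SOD2 and 1.20 for CEBPA.

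Among genes of growth, survival and stress, the differences were 2.13 for PLK2, 2.38 for ERRFI1, 1.44 for CDKN2B, 2.32 for CCNE2 and 1.09 for CENPE, and -1.65 for FAS, -0.78 for TP53I3, -1.51 for TYMS, -0.89 for MCM5, -2.22 for BCL2L1, -1.58 for TRIB3 and -1.01 for ATF3. Ribosome biogenesis and chromatin genes differed by -1.67 for RRS1, -1.41 for DKC1, -1.05 for MBD2 and -0.77 for MACROH2A1, and the glucocorticoid receptor gene NR3C1 by -1.36. Further positive differences were those of UTS2B (4.31), GPR50 (3.99), REXO1L1P (3.58), SNAI2 (3.53), CRISPLD2 (3.52), RFPL4A (3.06), ENPP2 (3.05), KRTAP19-8 (3.04), NEFM (1.94) and TENM1 (1.37). Further negative ones were those of CYP1B1 (-4.41), IL31 (-3.76), AVPR1A (-3.47), NDST4 (-3.08), BMPR1B (-2.67), ABCB10 (-2.45), PATZ1 (-2.43) and GBE1 (-1.56).

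More genes passed the drug test in L428-PAX5 than in L428, 6204 against 892. Array scaling is argued against as the whole cause, since under the 2 other scalings the ratio of the counts was at least 6.91. A single array is argued against too, since the interaction passed for at least 2171 genes without any 1 of the 12 arrays. Weaker drug exposure of L428 would have left its cancer-testis genes, which answer to demethylation, with less of a rise. Their median rise was 0.48 in L428 and 0.31 in L428-PAX5, a difference of 0.18 (resampled -0.22 to 0.39). The rise in L428 exceeded 0.5 times that in L428-PAX5 by 0.33 (0.05 to 0.81). For this list, that argues against a response below that share but not against a smaller deficit, and it bears on 5-aza-dC and not on TSA. Of the 24 genes, 15 in L428 and 13 in L428-PAX5 did not pass, and some may share signal. The resampled ranges may therefore understate the uncertainty. Of the 368 genes that changed at least 2-fold in L428, 108 changed more in L428-PAX5, though these genes were chosen for their change in L428. Line, PAX5 and the HEPES in the medium of L428-PAX5 are confounded, and which of them underlies the pattern stays open and was not tested.

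Interferon genes rose with the drugs in L428 (median 1.11) and had a negative median in L428-PAX5 (-0.57), with 8 of 30 genes passing in opposite directions. Under the other scalings the median in L428-PAX5 was at most -0.45, and without any 1 of the 12 arrays at least 22 genes had a passing negative difference, which argues against scaling and a single array. A higher starting level in L428-PAX5 is argued against by the medians before the drugs, which differed by -0.23 (resampled -0.42 to -0.12). They were 8.3, 8.11 and 8.23 on the L428-PAX5+M arrays and 8.49, 8.45 and 8.46 on the L428+M arrays. A lower start is not shown, since 4 genes passed as higher and 4 as lower there (camera adjusted p = 0.27). In L428-PAX5, 7 of the genes passed as higher and 14 as lower. The 2 drugs were always given together, and line, PAX5 and medium are confounded, so which of them underlies the difference stays open and was not tested.

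Splits of the same arrays into groups of the same sizes were counted for each comparison. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05, and in each such comparison only 1 split, the real one, reached the real count. The real count and the highest of the other splits were 2996 and 0 for PAX5 without drugs, 892 and 0 for the drugs in L428, 6204 and 0 for the drugs in L428-PAX5, 5898 and 1 for PAX5 with drugs, 6899 and 0 for both together and 3545 and 0 for Raji against Namalwa. For the B-cell genes that were higher they were 196 and 0 in L428-PAX5+M, 81 and 0 in L428+MAT and 289 and 0 in L428-PAX5+MAT. Of the 10 splits, 4 part all 3 pairs of equal numbers, and the highest other count among these was 0 in the first 6 comparisons.

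For the interaction 100 splits were drawn, and 1 of 100, the real one, reached 2990 genes, with a highest other of 2586. Such splits mix lines and drugs and so test for any difference among the groups. They cannot exclude chance for the interaction itself. In the second draw 1 of 60 splits gave 3147 genes, the next gave 786, and 53 gave none. Among 100 splits that keep 1 array of each replicate number in every group, 2 reached 2990, the real one and another at 3336, and with the number as a block 1 did, the real one at 4730, with a highest other of 4176. For the B-cell lines, only the real split reached its count against L428 (1 of 100, 6526 genes, highest other 5221), against L428-PAX5 (1 of 100, 6839 and 5495) and against L428-PAX5 with drugs (1 of 100, 9123 and 8129). These draws, too, test for any difference among the groups compared. The highest other splits kept the 3 arrays of 1 L428-derived group together, L428-PAX5+MAT for the interaction in each draw and the L428-derived group compared with the B-cell lines in the other 3, and so follow the structure of the groups.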

How the results depend on the processing

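Omission of the arrays numbered 3, and of L428-PAX5+MAT arrays 2 and 3, was chosen only after the data were seen. No named gene changed direction past the limit under the alternatives run for named genes. Counts of comparisons and lists were compared by size and not by direction. For PAX5 and the drugs together, heat shock genes had 4 higher and 7 lower, but 7 and 6 after quantile normalization. Of the counts per comparison, 126 of 153 stayed within 1.5 times and 27 moved, and all 111 did so when 1 array was left out. Without 1 array, the genes passing ranged from 2258 to 2722 for PAX5 without drugs, 621 to 861 for the drugs in L428, 4900 to 6351 for the drugs in L428-PAX5, 4966 to 6162 for PAX5 with drugs and 2171 to 3956 for the interaction.

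At a limit of 2-fold, 881 genes passed for PAX5 without drugs, 368 and 2033 for the drugs in L428 and L428-PAX5, 2097 for PAX5 with drugs, 1624 for the interaction, 2629 for PAX5 and drugs together, 2663, 2653 and 3843 for the B-cell lines against L428, L428-PAX5 and L428-PAX5 with drugs, and 1431 for Raji against Namalwa. These lower counts follow from the stricter limit. Array weights, whose estimation stopped before its tolerance was reached, gave 2551 and 9532 for the drugs in L428 and L428-PAX5, 11176 for PAX5 with drugs, 5965 for the interaction, 5747 for Raji against Namalwa, and 152 B-cell genes raised by the drugs in L428. The cause was not tested. The replicate number as a block gave 1592 for the drugs in L428 and 4730 for the interaction, and it removes the spread shared by equal numbers. With only the 2 groups in the fit, 593 passed for the drugs in L428, with fewer arrays to estimate the spread. Without L428-PAX5+MAT arrays 2 and 3, which leaves 1 array assumed to vary like the other groups, 3806 passed for the drugs in L428-PAX5 and 3915 for PAX5 with drugs.

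Of the B-cell genes at least 4-fold higher in both lines, 41, 44 and 85 were higher in L428-PAX5+M, L428+MAT and L428-PAX5+MAT, and 83, 43 and 138 of those at 2-fold were at least 2-fold higher. Of the named genes' results, 5253 of 5391 kept their side of the limit, 121 lost it and 17 gained it, and with 1 array left out 3611 of 3801 did, 187 lost and 3 gained it. Of the list counts, 3286 of 3888 stayed within 1.5 times and 602 moved, and with 1 array left out 2137 of 2448 and 311. Of the list tests rerun with the replicate number as a block, 3 of 168 changed their call, all named in the report. Signal near background limits what dim genes can show.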

Other observations

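The test of whether the arrays numbered 1 share the deviation of PAX5 was chosen only after the result was seen, and the tests of carry-over and of neighbouring genes were written before.

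The drugs shared part of their effect between the lines. Across genes, the changes in L428 and L428-PAX5, which use no array in common, correlated with r = 0.41 (Spearman 0.31). There were 421 genes higher in both, against 110.3 if the calls were independent, 74 lower in both against 22.8, and 73 passed in opposite directions. The PAX5 effects without and with drugs correlated with r = 0.49 (Spearman 0.36), with 776 genes higher in both against 256.8, 823 lower in both against 213.2, and 173 in opposite directions. The PAX5 effect without drugs and the B-cell lines against L428 correlated with r = 0.28 (Spearman 0.31). Here 781 genes were higher in both against 335.6, 712 lower in both against 201.2, and 459 in opposite directions. The drug effect in L428 and the PAX5 effect with drugs correlated with r = 0.01 (Spearman 0.04). Here 192 were higher in both against 111.2, 60 lower in both against 20.7, and 313 in opposite directions. Each of these last pairs shares a group of arrays. L428+M is subtracted in both comparisons of the former pair, which pushes its correlation up. L428+MAT enters the latter pair with opposite signs, which pushes its correlation down. Genes are not independent replicates, and 4 such relations were computed.

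The PAX5 signal of L428+M replicate 1 (8.64) stood above those of replicates 2 and 3 (7.14 and 6.7). A deviation shared by the arrays numbered 1 is argued against, since PAX5 lay 0.05 above its group mean on the other 5 such arrays. Carry-over of L428-PAX5 RNA could explain the signal with a share of 4.2%, which predicts a median excess of 0.50 for 15 genes far higher in L428-PAX5. The observed excess was 0.25 (resampled -0.02 to 0.38), against -0.33 and 0.05 in the other replicates, and 11 of 15 genes (73.3%, against 33.3% by chance) lay above both. Carry-over therefore stays open, as does a true difference in PAX5 expression, and no biological explanation was tested. Carry-over would also bring L428+M closer to L428-PAX5+M and so lower the share of the B-cell gap closed in L428-PAX5+M. That share was 6.5% with all arrays and 10.8% without L428+M replicate 1. It was 7.8% without replicate 2 and 7.5% without replicate 3. Whether carry-over underlies the larger share without replicate 1 was not tested.

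A copy number difference between L428-PAX5 and L428 was tested as a hypothesis, since a derived line may gain or lose chromosome segments. Of 356 blocks of 50 neighbouring genes (18365 genes placed), 4 blocks had a median PAX5 effect further from the median of all genes than 0.21, the distance that 95% of 1000 shuffled gene orders stayed within, and all 4 were higher and shifted the same way with the drugs present. They ran from ZNF626 to SLC7A10 (median 0.20 without and 0.44 with drugs), PLEKHG4B to OTULIN (0.32 and 0.26), ANKH to EGFLAM (0.22 and 0.23) and DYNC2I2 to UCK1 (0.21 and 0.21). In the drug effect in L428, where copy number cannot differ between the groups, 2 blocks also passed, so a copy number difference is a candidate explanation that neighbouring genes with shared regulation could also produce.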
